A study of Mus musculus with 8 samples.

How the data were processed

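RNA from tibialis anterior muscle of mice with a muscle-specific ATF4 deletion was compared between 4 arrays of muscles transfected with empty plasmid (left) and 4 of muscles transfected with Gadd45a plasmid (right). Per the labels' protocols, total RNA was extracted with TRIzol, amplified to cDNA with NuGEN kits, fragmented and labelled with biotin. The deposited values are log2 intensities, 1 per probe set and array, and the submitters' processing notes name GCOS, RMA and the mouse build mm9, without versions. RMA corrects background, quantile-normalizes the arrays and summarises probes, so differences in overall brightness between arrays are largely removed and small changes of very dim or very bright probe sets are compressed. How the deposited probe sets were selected is not given in the sources used here. The values held 0 missing entries, and array medians ran from 5.852 to 5.919.

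Groups were taken from the titles and treatment labels. Of 16755 probe sets, 14996 had 1 gene symbol in the array's annotation, 1019 had several and 740 had none listed; genes were named only from the first kind. Gene identifiers of 14941 probe sets were found in a RefSeq table of assembly GRCm38.p6, which was used only for names, and 0 symbols changed. Because that assembly differs from mm9, no coordinates are given. The 14860 genes include 135 with more than 1 probe set; gene lists used the probe set with the highest mean over all 8 arrays.

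Tests were run on the log2 values as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with no block for sample number and Benjamini-Hochberg adjustment over all probe sets; the threshold was an adjusted p of 0.05. SE is the moderated standard error of the log2 fold change, Gadd45a plasmid minus control plasmid. Gadd45a was also tested by an exact permutation over the 70 labellings. The 30 gene lists (740 symbols, 600 measured), which cover metabolism, contraction, protein breakdown, stress pathways and the other cell types of dissected muscle, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation, camera on ranks and the rotation test fry were run beside it. An exact permutation test of list means was added after other splits of the arrays were seen to give as many lists with camera.

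The named genes followed a fixed rule: Gadd45a and Atf4; the 12 largest increases and 12 largest decreases among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between groups; and from each list up to 4 changed members with the largest changes, or the 2 largest where fewer than 2 changed. From the largest changes, some symbols were left out of the naming but not of the counts. These were numbered Gm and LOC symbols, those ending in Rik, those starting Olfr, Vmn, Mir or Snor, and accessions. Other second probe sets and the following genes were chosen after their values were seen: Sh3rf2, Lrp4, Tfb1m, Cacng1, Ccng1, Phlda3, Mt1, Mt2, Col12a1, Cd34, and the genes named for the first time in the closing section. The design, tests, lists, naming rule and alternatives were set before the data were examined, except cyclic loess, the exact list test, the held-out lists and, other than the splits of the arrays, the tests of explanations in the closing section. Of these, the tests on held-out lists and on intensity were set before their own results were seen.

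Alternatives were the sample number as a block, quantile normalization, median centring, cyclic loess, leaving out the probe sets below the median brightness, trend and robust variance, array weights, 1 probe set per gene, other thresholds, the mean of a gene's probe sets, and leaving out each array or each same-numbered pair in turn. The fit was tested on simulated data for this comparison, with 200 of 16755 probe sets changed: it recovered 61.2% of changes of 0.5 log2 units, 91% of changes of 1 and 100% of changes of 2, with 13 unchanged probe sets called, and 0 calls with no simulated change. When 1 list was shifted by 0.3, camera called 1 list, and with none shifted it called 0. The simulation drew genes independently and does not cover correlated genes.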

Results

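RNA was measured on 8 microarrays from the tibialis anterior, a fast muscle of the lower hindlimb, of 8-week-old male mice that lack ATF4 in skeletal muscle. ATF4 is a stress-responsive transcription factor, and Gadd45a is a small nuclear stress protein known to be induced in muscle during atrophy. In each group 4 arrays were available. The control group had received an empty expression plasmid in the left muscle, and the other group had received a plasmid encoding tagged Gadd45a in the right muscle. Muscles were taken on day 7 after transfection. The comparison asks which transcripts differ when Gadd45a is forced into muscle fibres that lack ATF4. Because the Gadd45a plasmid always went into the right muscle, plasmid and side cannot be told apart. Because the control plasmid was empty, an effect of Gadd45a cannot be told apart from that of making any tagged protein. The labels do not say that the arrays of a group came from separate mice, so p-values measure the spread between these arrays, which may be partly technical. The number of arrays limits the precision of every value below.

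Gadd45a itself rose from 7.76 ± 0.08 log2 units (SD, n = 4) with control plasmid to 10.33 ± 0.12 (SD, n = 4) with Gadd45a plasmid. The log2 fold change was 2.57 (SE 0.08, adjusted p = 7.74e-07), a 5.94-fold higher signal, and all 4 Gadd45a arrays lay above all 4 control arrays. An exact two-sided permutation test of these values gave p = 0.0286, the smallest that the 70 labellings of the arrays allow. The probe set does not separate plasmid RNA from RNA of the mouse's own gene. Atf4, whose gene was deleted in muscle in both groups, read 6.95 ± 0.09 and 7.49 ± 0.10 (SD, n = 4 each), a rise of 0.54 (SE 0.08, adjusted p = 0.00136). No muscle with intact ATF4 was analysed here, so these readings do not check the deletion.

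**Figure D1:**
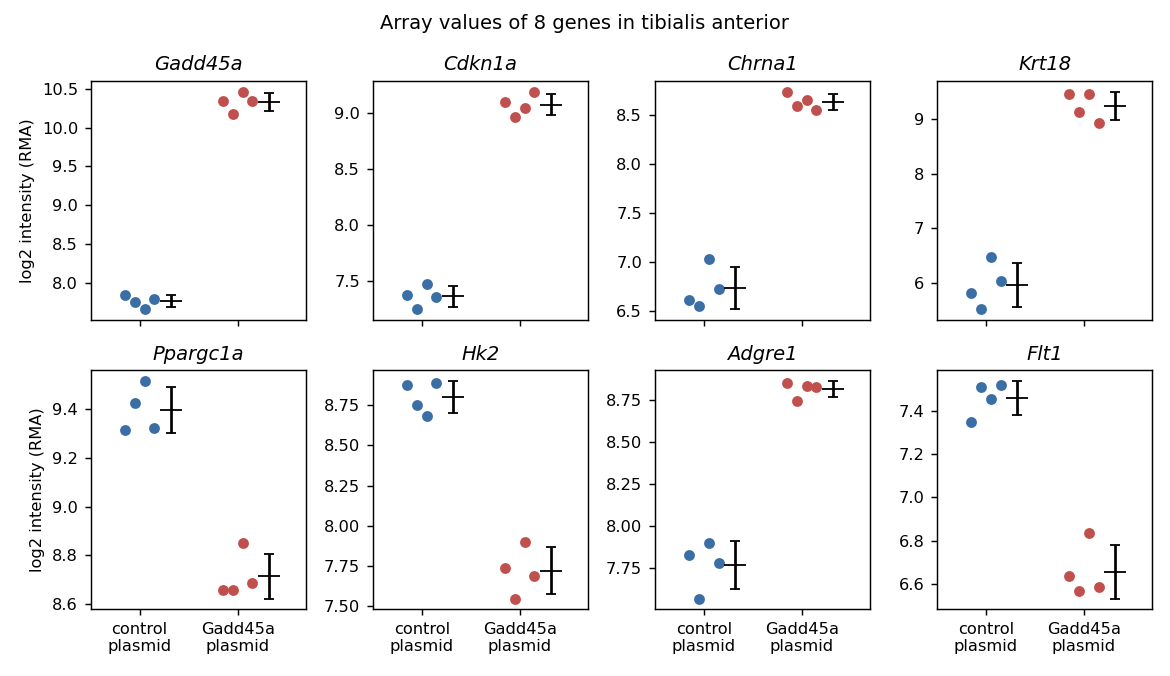
Array values (log2 intensity, vertical axes that do not start at 0) of 8 genes in the control plasmid group (blue) and the Gadd45a plasmid group (red); each point is 1 of 4 arrays, and the black bar shows the mean with its SD. Gadd45a, Cdkn1a, Chrna1, Krt18 and Adgre1 were higher and Ppargc1a, Hk2 and Flt1 lower in all 4 Gadd45a arrays, with no overlap between the groups.

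Of 16755 probe sets, 3542 (21.1%) changed at an adjusted p under 0.05, 1814 higher and 1728 lower with Gadd45a plasmid. In 3308 of them the groups did not overlap, 1733 higher and 1575 lower. At least 2-fold changes were fewer and mostly increases, with 129 higher and 51 lower. The median log2 fold change over all probe sets was -0.065. At an unadjusted limma p under 0.05, more probe sets were lower (3388) than higher (2712). Among all probe sets 4508 (26.9%) had groups that did not overlap, against 2.86% expected by chance for 4 against 4 arrays. The first principal component carried 47% of the variance and separated the groups, with control arrays between -25.5 and -16.4 and Gadd45a arrays between 18.6 and 23. Correlations between arrays ran from 0.979 to 0.986 within the control group, from 0.986 to 0.989 within the Gadd45a group, and from 0.963 to 0.975 between the groups. The second component (12.6%) set control 1 apart, at 23.2, and the 5th percentile of intensity was 3.51 to 3.64 on the control arrays and 3.41 to 3.45 on the Gadd45a arrays. The count of changed probe sets fell to 1876 without both arrays numbered 2, to 2027 without those numbered 4, to 2170 without those numbered 1 and to 2321 without those numbered 3.

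Among genes open to naming, with an adjusted p under 0.05 and no overlap between the groups, the largest increase was in Krt18, which encodes a keratin of intermediate filaments, from 5.96 ± 0.41 to 9.24 ± 0.25 (SD, n = 4 each; log2 fold change 3.28, SE 0.20, adjusted p = 2.51e-05). Mmp12, the elastase of macrophages, rose by 2.84 (SE 0.24, adjusted p = 9.57e-05). The other named increases were in Gabrb2, a subunit of the GABA receptor (2.38, SE 0.35), Atp1b4, a muscle relative of the sodium pump's beta subunits (2.32, SE 0.10), Casq2, the cardiac and slow-muscle calsequestrin (2.26, SE 0.17), and Ncam1, the neural cell adhesion molecule (2.13, SE 0.12). They continued with Sln, the sarcolipin that regulates the calcium pump (2.12, SE 0.19), Tnni1, the slow-fibre troponin I (2.10, SE 0.11), Mymk, the myoblast fusion protein myomaker (1.97, SE 0.16), Chrna1, the alpha subunit of the muscle acetylcholine receptor (1.91, SE 0.11), and C1qtnf3, a secreted protein (1.90, SE 0.15). A second probe set of Gabrb2 rose by 1.14.

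By the same criteria the largest decrease was in the tetraspanin Tspan8, from 9.16 ± 0.15 to 7.29 ± 0.41 (SD, n = 4 each; log2 fold change -1.87, SE 0.18, adjusted p = 0.000188). Ibsp, the bone sialoprotein, followed at -1.73 (SE 0.20), and Tgtp1, an interferon-inducible GTPase with a near-identical neighbour that the probes may not tell apart, at -1.67 (SE 0.28) and -1.51 on its other probe set. Pfkfb3, an enzyme that makes an activator of glycolysis, fell by 1.48 (SE 0.08, adjusted p = 2.07e-05). The remaining named decreases were Scn4b, a sodium channel subunit (-1.39, SE 0.18), Smco1 (-1.36, SE 0.10), the retinaldehyde dehydrogenase Aldh1a1 (-1.32, SE 0.12), the lipoprotein receptor Vldlr (-1.28, SE 0.10), the interferon-inducible Gbp7 (-1.28, SE 0.21), the muscle fructose bisphosphatase Fbp2 (-1.25, SE 0.09), the phosphodiesterase Gpcpd1 (-1.24, SE 0.08) and the spermine oxidase Smox (-1.23, SE 0.16).

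Genes known to respond to denervation were higher: 16 of 23 measured members rose and 2 fell, with a median log2 fold change of 0.91 (16 rose and 3 fell adjusted over the list alone). Besides Ncam1, Sln and Chrna1, the cardiac troponin T gene Tnnt2 rose by 1.90 (SE 0.15, adjusted p = 7.93e-05). The members that fell were Fbxo32, an atrophy-related ubiquitin ligase (-0.74), and Sh3rf2 (-0.82). As a group the list was higher with camera (adjusted p = 6.42e-11), with adjusted p = 0.0523 with an estimated correlation. The neuromuscular synapse list shares Chrna1, Chrnb1, Chrnd and Musk with the denervation list, so they are not independent. Of the 17 synapse genes 7 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone. Examples were the acetylcholine receptor subunits Chrnd (1.01, SE 0.11) and Chrnb1 (0.75, SE 0.12) and the protein kinase A subunit Prkar1a (0.80, SE 0.08), while Lrp4, the agrin receptor, was the member that fell (-0.21, adjusted p = 0.0326, a call lost in all 12 fits that left out an array or a same-numbered pair). Camera placed this list higher (adjusted p = 4e-04), with adjusted p = 0.0523 with an estimated correlation.

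Contractile genes moved both ways. Of 21 sarcomere genes 2 rose and 8 fell (3 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.118). The slow-fibre troponins Tnni1 (2.10) and Tnnc1 (1.77, SE 0.19) rose, the fast myosin-binding protein Mybpc2 fell by 0.70 (SE 0.07), and the slow-fibre light chain Myl2 fell by 0.69 (SE 0.18) with overlapping groups, a call lost in 8 of the 12 fits without an array or a pair. Of 22 genes of calcium handling and excitation 3 rose and 12 fell (3 and 14 adjusted over the list alone), with a median of -0.28. Casq2 (2.26), the slow and cardiac calcium pump Atp2a2 (1.07, SE 0.09) and the calcium channel subunit Cacng1 (0.51, SE 0.09) rose. The neuronal nitric oxide synthase Nos1, which is abundant in fast fibres, fell by 1.01 (SE 0.09) and the chloride channel Clcn1 by 0.70 (SE 0.07). This list was lower with camera (adjusted p = 0.0426), with adjusted p = 0.215 with an estimated correlation. Its p rose above the threshold without control 2 (0.0526), control 3 (0.0782), control 4 (0.067), Gadd45a 4 (0.0534), the arrays numbered 3 (0.0914) or those numbered 4 (0.0839), and was 0.0784 with the sample number as a block and 0.0543 with the mean of probe sets.

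Genes of energy metabolism were lower. Of 18 genes of glycolysis and glycogen 15 fell and 0 rose, also adjusted over the list alone, with a median of -0.60. Besides Fbp2, the phosphorylase kinase subunits Phka1 (-1.15, SE 0.08) and Phkg1 (-1.06, SE 0.07) and the hexokinase Hk2 (-1.08, SE 0.09, adjusted p = 9.57e-05) fell in all 4 Gadd45a arrays. Of 17 genes of the TCA cycle and pyruvate entry 12 fell (14 adjusted over the list alone; median -0.35), led by the aminotransferase Got1 (-0.83), the pyruvate dehydrogenase subunits Pdhb (-0.74) and Pdha1 (-0.59), and the isocitrate dehydrogenase subunit Idh3a (-0.58). Of 25 genes of fatty acid uptake and oxidation 16 fell (18 adjusted over the list alone; median -0.39), among them the fatty acid transporter Cd36 (-0.69), the dehydrogenase Acadm (-0.65), and the lipases Pnpla2 (-0.61) and Lpl (-0.60). Cd36 is also abundant in endothelium and adipocytes, and Pnpla2 and Lpl in adipocytes, and the lists of these cells had medians of -0.29 and -0.30 (below), so their fall need not come from fibres. Of 51 oxidative phosphorylation genes 27 fell and 0 rose (38 fell adjusted over the list alone; median -0.29), with the complex I subunits Ndufa3 (-0.65), Ndufb2 (-0.63) and Ndufs6 (-0.63) and the cytochrome oxidase subunit Cox8b (-0.62) lowest.

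With camera, adjusted p was 1.51e-11 for glycolysis and glycogen, 2.53e-07 for the TCA cycle, 2.53e-07 for fatty acid oxidation and 6.85e-11 for oxidative phosphorylation, all lower. In the same order the lists had adjusted p = 0.0523, 0.154, 0.154 and 0.203 with an estimated correlation. Among 18 genes of the PGC-1 coactivators and mitochondrial biogenesis 9 fell and 1 rose (9 and 2 adjusted over the list alone). The coactivator Ppargc1a fell by 0.68 (SE 0.08, adjusted p = 0.000372), the mitochondrial fusion genes Mfn2 by 0.76 (SE 0.07) and Mfn1 by 0.68 (SE 0.08), and the nuclear receptor Ppara by 0.54 (SE 0.09). The member that rose, the mitochondrial RNA methyltransferase Tfb1m (0.38, adjusted p = 0.0431), lost its call in 10 of the 12 fits without an array or a pair. The list was lower with camera (adjusted p = 0.0187), with adjusted p = 0.154 with an estimated correlation.

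Genes linked to muscle protein breakdown moved both ways. Among 17 ubiquitin ligases and atrophy genes 4 rose and 5 fell (4 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.284). The growth inhibitor myostatin, Mstn, fell by 0.97 (SE 0.11, adjusted p = 0.000419) and Fbxo32 by 0.74 (SE 0.12). The ubiquitin ligases Fbxo30 (0.59, SE 0.09) and Mdm2 (0.56, SE 0.08) and the metallothioneins Mt1 (0.40) and Mt2 (0.38, a call lost in 6 of the 12 fits without an array or a pair) rose. Of 27 proteasome subunits 6 rose and 1 fell (7 and 1 adjusted over the list alone), with small changes such as 0.31 for Psma2, 0.30 for Psmc1 and 0.28 for Psmb1 (calls lost in 10, 3 and 5 of the 12 fits without an array or a pair), while the proteasome activator Psme4 fell by 0.44. Camera placed the proteasome list higher (adjusted p = 0.00515, median 0.09), with adjusted p = 0.374 with an estimated correlation and 0.091 without probe sets below the median brightness. Of 31 autophagy and lysosome genes 5 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.811). The lysosomal proteases Ctsb (0.69) and Ctsd (0.47), which macrophages also make and whose source these arrays cannot separate, rose, and the lysosomal regulator Tfeb (-0.48) and the autophagosome protein Map1lc3b (-0.39) fell.

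Of 18 apoptosis genes 4 rose and 2 fell, also adjusted over the list alone, without a shift of the list (camera adjusted p = 0.278). Casp12, a caspase of the endoplasmic reticulum, fell by 1.12 (SE 0.12) and the death receptor Fas by 0.44, while the pro-apoptotic Bcl2l11 rose by 0.45 and Casp6 by 0.44. Of 20 genes of insulin and IGF-1 signalling 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.209). Grb10, an adaptor that dampens insulin receptor signalling, rose by 1.28 (SE 0.09, adjusted p = 6.36e-05) and the growth factor Igf1 by 0.77 (SE 0.12). Foxo4 (-0.33) and Tsc1 (-0.25) fell, the latter losing its call in 7 of the 12 fits without an array or a pair.

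Genes induced by p53 included several of the stronger increases, of which Cdkn1a and Eda2r are also in the denervation list. The cyclin-dependent kinase inhibitor Cdkn1a rose from 7.37 ± 0.09 to 9.08 ± 0.09 (SD, n = 4 each; 1.71, SE 0.08, adjusted p = 8.77e-06), the receptor Eda2r by 1.60 (SE 0.15), the spindle protein Ckap2 by 1.12 (SE 0.20) and the kinase Plk2 by 0.81 (SE 0.08). In this list of 21 genes 7 rose and 3 fell, also adjusted over the list alone, and it did not pass (camera adjusted p = 0.0571; median 0.01). The members that fell were Fas, Ccng1 (-0.29) and Phlda3 (-0.24). Of the 12 fits without an array or a pair, Fas lost its call in 2, Ccng1 in 3 and Phlda3 in all 12. The list's p was below the threshold without control 1 (0.0469), control 4 (0.0444), Gadd45a 2 (0.0397), Gadd45a 3 (0.0463), the arrays numbered 2 (0.0436) or those numbered 4 (0.0472). It was highest, at 0.0976, without control 3. With all arrays the list had adjusted p = 0.154 with an estimated correlation, 0.194 with camera on ranks and 0.000243 with fry.

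Of 28 ATF4 targets 4 rose and 5 fell (5 and 7 adjusted over the list alone), with no shift in either direction (camera adjusted p = 0.811). The asparagine synthetase gene Asns rose by 1.03 (SE 0.12), while Vldlr (-1.28), the glutathione-degrading Chac1 (-0.90, SE 0.12) and the tRNA synthetase gene Wars (-0.65, SE 0.19, a call lost in 8 of the 12 fits without an array or a pair) fell. Among 10 genes of the Gadd45 family and DNA demethylation 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.31). The methylcytosine dioxygenase Tet2 rose by 0.79 (SE 0.08, adjusted p = 0.000199), the DNA methyltransferase Dnmt1 by 0.37 (SE 0.07) and the endonuclease Apex1 by 0.40 with overlapping groups, a call lost in 8 of the 12 fits without an array or a pair. Gadd45b fell by 0.25 (adjusted p = 0.0492), a call lost in 11 of the 12 fits without an array or a pair. Of 8 polyamine genes Smox fell and the antizyme inhibitor Azin1 rose by 0.57 (1 higher and 1 lower, also adjusted over the list alone; camera adjusted p = 0.811). Of 16 immediate early and heat shock genes, read as a sign of tissue handling, Egr2 (0.52) and Btg2 (0.43) rose, the latter with overlapping groups and a call lost in 9 of the 12 fits without an array or a pair (2 higher and 0 lower, also adjusted over the list alone; camera adjusted p = 0.307).

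Proliferation genes were higher, with 15 of 23 rising and 0 falling (16 and 0 adjusted over the list alone; median 0.52). The spindle gene Prc1 rose by 0.95 (SE 0.14), the motor Kif11 by 0.91 (SE 0.13), the topoisomerase Top2a by 0.90 (SE 0.10) and the checkpoint kinase Bub1 by 0.86 (SE 0.11). The list was higher with camera (adjusted p = 1.51e-11), with adjusted p = 0.0662 with an estimated correlation. Of 16 genes of satellite cells and myoblasts 6 rose and 0 fell (7 and 0 adjusted over the list alone). Mymk (1.97) and the differentiation factor Myog (0.99, SE 0.12) led, and the adhesion molecule Vcam1 (0.42) and the repressor Msc (0.41) changed less and lost their calls in 7 and 9 of the 12 fits without an array or a pair, Msc with overlapping groups. Myog is also in the denervation list, so these lists are not independent. Camera placed the satellite cell list higher (adjusted p = 0.00057), with adjusted p = 0.143 with an estimated correlation and 0.091 without probe sets below the median brightness.

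Markers of macrophages and monocytes were higher in the same muscles. Of 20 measured genes 15 rose and 0 fell (17 and 1 adjusted over the list alone; median 0.58). Gpnmb, a glycoprotein of tissue macrophages, rose by 1.52 (SE 0.12, adjusted p = 7.42e-05), the complement gene C1qa by 1.23 (SE 0.20), the macrophage surface receptor Adgre1 by 1.05 (SE 0.08) and the lysosomal Cd68 by 1.05 (SE 0.10). With camera the list was higher (adjusted p = 5.9e-12), with adjusted p = 0.115 with an estimated correlation. Lymphocyte genes did not shift as a list (2 of 16 higher and 2 lower, also adjusted over the list alone; camera adjusted p = 0.485): the T cell receptor genes Cd3g (0.78) and Cd3e (0.46) rose, and the granzymes Gzmb (-0.96) and Gzma (-0.51, a call lost in 8 of the 12 fits without an array or a pair) fell. Of 16 neutrophil and mast cell genes 1 rose and 3 fell (1 and 9 adjusted over the list alone; median -0.33). The myeloperoxidase Mpo (-0.83), the chemokine receptor Cxcr2 (-0.63) and the tryptase Tpsb2 (-0.22, and -0.47 on its other probe set) fell and the receptor Csf3r (0.47) rose. Cxcr2, whose groups overlap, lost its call in 8 of the 12 fits without an array or a pair, Tpsb2 in 10 and Csf3r in 7; Cxcr2 also lost it under all 3 other normalizations, and Tpsb2 after quantile normalization, cyclic loess and with the sample number as a block. The list did not pass (camera adjusted p = 0.11), but its p was 0.00353 without Gadd45a 3, 0.0424 without control 2, 0.0295 without the arrays numbered 2 and 0.0128 without those numbered 3.

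Of 22 genes of antigen presentation and the interferon response 3 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.811). The guanylate-binding proteins Gbp2 (-0.89, SE 0.22) and Gbp3 (-0.76, SE 0.17) fell, as did the chemokine Cxcl9 (-0.61, adjusted p = 0.0499, with overlapping groups, lost in 8 of the 12 fits without an array or a pair), while the class II gene H2-Aa rose by 0.51 (SE 0.09). Gbp2 and Gbp3 lost their calls in 3 and 1 of these 12 fits. Of 23 cytokine and chemokine genes 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.22). Ccl3 (0.71) and Tgfb1 (0.60) rose, and Ccl2 (-0.61) and Il15 (-0.56) fell, Il15 with overlapping groups and a call lost in 8 of the 12 fits without an array or a pair, and Ccl3 losing its call in 3.

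Connective tissue genes were higher and vascular genes lower. Of 27 fibroblast and extracellular matrix genes 17 rose and 2 fell (18 and 3 adjusted over the list alone; median 0.39). The matrix protein periostin, Postn, rose by 1.83 (SE 0.17, adjusted p = 0.000144), the collagen Col14a1 by 1.34 (SE 0.08), fibronectin, Fn1, by 1.15 (SE 0.11) and the microfibril protein Mfap5 by 0.84 (SE 0.07), while the collagen Col12a1 (-0.71) and the progenitor marker Cd34 (-0.43) fell. The list was higher with camera (adjusted p = 1.74e-10), with adjusted p = 0.15 with an estimated correlation. Of 24 genes of endothelium and mural cells 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.29). The VEGF receptor Flt1 fell by 0.80 (SE 0.08, adjusted p = 0.000216), the angiopoietin receptor Tek by 0.58 (SE 0.07) and the smooth muscle myosin Myh11 by 0.81 (SE 0.09), whereas the smooth muscle actin Acta2, also made by myofibroblasts, rose by 0.82 (SE 0.13). Camera placed the list lower (adjusted p = 8.82e-05), with adjusted p = 0.0523 with an estimated correlation.

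Of 15 adipocyte genes 8 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0761; median -0.30). Adiponectin, Adipoq, fell by 0.73 (SE 0.10), the desaturase Scd1 by 0.57 and the carbonic anhydrase Car3, which muscle also makes, by 0.48, while the lipogenic regulator Thrsp rose by 0.64 (SE 0.08). Of 14 Schwann cell and nerve genes 2 rose, Egr2 (0.52) and the neuregulin receptor Erbb3 (0.36), and the myelin gene Pmp22 fell by 0.33 (2 and 1 also adjusted over the list alone, camera adjusted p = 0.518). Erbb3 and Pmp22 lost their calls in 3 and 5 of the 12 fits without an array or a pair.

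**Figure D2:**
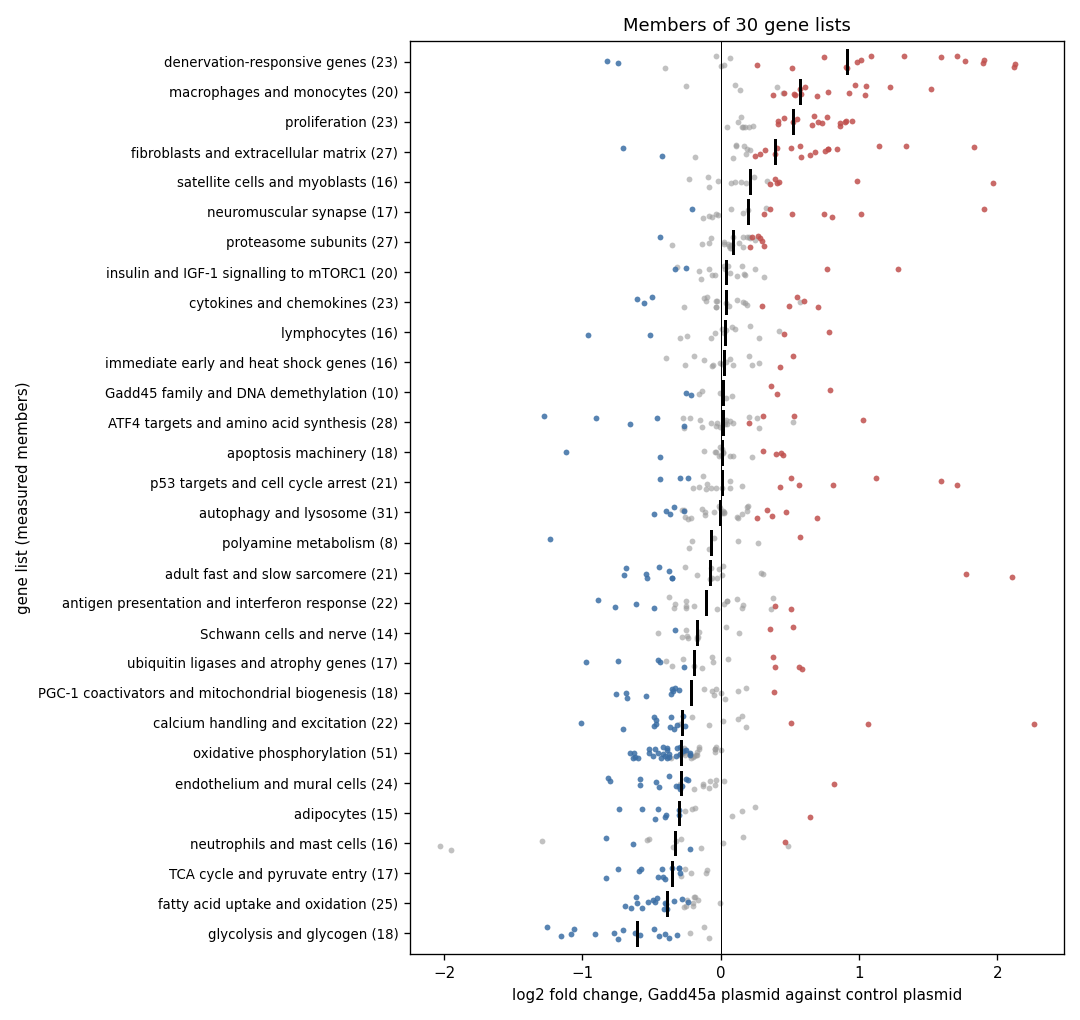
Log2 fold change (horizontal axis, Gadd45a plasmid against control plasmid) of each measured member of the 30 gene lists, with the number of measured members in parentheses; red and blue points are genes higher or lower at an adjusted p under 0.05, grey points are the others, and the black bar is the median of the list. Medians run from -0.60 for glycolysis and glycogen to 0.91 for the genes that respond to denervation.

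In all, 14 of the 30 lists passed with camera at its preset correlation, 7 higher and 7 lower. With the correlation estimated from the arrays 0 lists passed, and 0 passed an exact permutation test of list means, in which 16 lists, 12 of these 14 among them, reached the smallest p that the design allows (0.0286, adjusted 0.0536). The rotation test fry, which asks only whether a list's own genes move one way, passed all 14. The median, the mean and the camera direction differed in sign for autophagy, ATF4 targets and polyamine genes.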

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

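In 15 of 322 groups of 4 arrays, 1 array lay far from the other 3 relative to the group's range; chance gives about 1 in 20. The tests of fibre share, of a general rise of leukocytes and of left against right muscle in this part were chosen after the results were seen.

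Among arrays with control plasmid, control 1 lay apart for Tspan8 (9.38), Tgtp1 (9.27), Chrnd (5.65) and the mean of the calcium handling list (8.35). Control 2 lay apart for Ibsp (8.54), Psmb1 (9.49) and Pmp22 (8.39), control 3 for the mean of the ATF4 target list (6.58), and control 4 for Apex1 (7.47) and the mean of the polyamine list (6.69). Among arrays with Gadd45a plasmid, Gadd45a 1 lay apart for Ncam1 (8.1) and Btg2 (7.48), and Gadd45a 3 for Ppargc1a (8.85), Grb10 (7.52) and Cxcr2 (5.77).

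The number of changed probe sets, 3542, was reached by 1 of the 35 splits of the 8 arrays into 4 and 4, the real one. The highest of the other splits gave 3. Those splits mix the groups, so the group difference adds to the spread within them and lowers their counts. The real grouping therefore stood out, but so few splits cannot exclude chance. The number of lists past the camera threshold, 14, was reached by 4 of the 35 splits, and the highest of the others gave 16. By the rule set beforehand, chance was not excluded for that number. However, the other splits with 9 to 16 lists kept 3 arrays of a group together, and so part of the group difference. Splits that mixed the groups evenly gave 0 to 5 lists. This test therefore does not decide how many lists chance would give.

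The lower energy metabolism genes were weighed against technical explanations. If a smaller share of fibre RNA came with an even rise of every other cell type, their markers would rise alike. The endothelial median instead lay 0.86 log2 units below the macrophage median (difference -0.86, 95% bootstrap interval -1.143 to -0.692, over genes and not over arrays). This argues only against such an even rise. A smaller fibre share alone would also lower fibre genes alike. Quartiles of the log2 fold change ran from -0.874 to -0.383 for glycolysis genes, below the -0.371 to 0.008 of sarcomere genes. This argues against fibre share as the only cause for glycolysis genes, though very bright probe sets are compressed. The other energy lists overlapped the sarcomere quartiles, and calcium handling genes had a median of -0.283. A smaller fibre share as part of the fall, with unequal changes of the other cell types, was not tested and stays open. An intensity-dependent difference between arrays is argued against by 10000 random lists matched on mean level: their medians ran from -0.123 to 0.104, and 0 were as low as the -0.349 of the 111 energy genes. Left against right muscle cannot be told apart from the plasmid, because 0 right muscles with control plasmid were analysed. A response to Gadd45a stays open as a hypothesis beside the side of the muscle, the making of any tagged protein, and a smaller fibre share as part of the fall.

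For the higher macrophage genes, a held-out list of 30 other genes that macrophages make was written before its test. Of its 23 measured genes 16 rose and 0 fell, including the protease Lgmn (1.19), the lectin Clec4n (1.18) and the receptor Cd84 (1.06). Several members, such as Cd52, Cd53, Laptm5 and Lcp1, are also made by other leukocytes and do not separate the cell types. Camera gave p = 3.32e-15 for the held-out list and p = 0.0137 with an estimated correlation. The list was written after the first pattern was seen and was tested on the same arrays. It therefore extends the pattern to more genes and is not independent support for more macrophage RNA. Without an array or a pair the list's camera p at the preset correlation stayed between 2.66e-16 and 3.93e-14. The macrophage median exceeded the lymphocyte median by 0.55 (95% bootstrap interval 0.334 to 0.834) and the neutrophil median by 0.911 (0.678 to 1.338), over genes and not over arrays. This argues only against a general rise of equal size in all leukocytes. A smaller rise of lymphocytes beside the macrophage genes was not excluded. Whether macrophages were more numerous or more active was not tested, and left against right muscle cannot be told apart from the plasmid (0 right muscles with control plasmid).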

How the results depend on the processing

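Cyclic loess and the exact list test were chosen after seeing the data. No named gene reversed direction under any alternative, and 97 of the 129 genes named by the rule kept their call in all 12 fits that left out an array or a same-numbered pair; 32 lost it in at least 1. Calls lost in most of these fits were those of Gadd45b (11), Psma2 (10), Tpsb2 (10), Btg2 (9), Msc (9), Apex1, Cxcl9, Cxcr2, Gzma, Il15, Myl2 and Wars (8 each), and Csf3r, Tsc1 and Vcam1 (7 each). Calls were also lost after median centring (Gadd45b, Cxcr2, Cxcl9, Asb4, Lrp4 and Phlda3), cyclic loess (Cxcr2, Tpsb2, Cxcl9, Asb4, Lrp4 and Tfb1m), quantile normalization (Cxcr2, Tpsb2, Cxcl9, Asb4 and Tfb1m) and with array weights (Msc and Asb4). Gadd45a kept a log2 fold change between 2.49 and 2.62. The total of changed probe sets was 1876 to 3174 in those fits (1055 to 1666 higher, 821 to 1516 lower), 1630 at an adjusted p under 0.01 (944 higher, 686 lower), and 5189 at an adjusted p under 0.1 (2395 higher, 2794 lower), so that higher calls outnumber lower ones at 0.01 and 0.05 and lower ones outnumber higher ones at 0.1. Fits without arrays use fewer samples. The share of higher calls was 51.2% as deposited, 54% after quantile normalization, 57.5% after centring and 56.1% after cyclic loess.

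Same-numbered arrays deviated together only weakly (r 0.045 to 0.097, below the 0.1 set for pairing), though all 8 arrays correlated best with their own number (highest other r 0.028), a hint from the data and not from the design. With the replicate block 3171 probe sets changed, 2883 of them among the 3542, and the calcium handling list had adjusted p = 0.0784; no other list changed its call, and 9 named genes lost theirs (Psma2, Gadd45b, Tpsb2, Erbb3, Asb4, Socs1, Lrp4, Tfb1m and Phlda3).

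With an estimated correlation 0 lists passed: glycolysis, denervation, synapse and endothelium 0.0523, proliferation 0.0662, macrophages 0.115, satellite cells 0.143, fibroblasts 0.15, TCA cycle, fatty acids and PGC-1 0.154, oxidative phosphorylation 0.203, calcium handling 0.215 and proteasome 0.374. In the exact permutation test 0 passed: proteasome 0.0952, calcium handling 0.171 and the other 12 at 0.0536, the smallest possible for these data. Fry added ubiquitin ligases 0.00266, sarcomere 0.0138, p53 targets 0.000243, the Gadd45 family 0.0149 and adipocytes 0.00207. Ranks added neutrophils 0.0436 and adipocytes 0.0378. Adipocytes were 0.0399 after quantile normalization and 0.0344 after cyclic loess. Without probe sets below the median brightness, proteasome and satellite cells were 0.091 and sarcomere 0.0419; with trend and robust variance sarcomere was 0.0444; with the mean of probe sets calcium handling was 0.0543. Without an array or a pair, sarcomere ran from 0.0469 (without control 1) to 0.279, calcium handling from 0.0198 to 0.0914, neutrophils from 0.00353 (without Gadd45a 3) to 0.281 and p53 targets from 0.0397 to 0.0976. The cause of these moves was not tested. A pseudocount for linear values was not run, because the values are on a log2 scale. No signal over background was given, so limits for dim probe sets are unknown.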

Other observations

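The genes named in the first 2 paragraphs were chosen after their values were seen; the held-out lists were written before the values of their members were looked at, but after the patterns they follow. Several imprinted genes of fetal growth were among the stronger increases. Peg3, a zinc-finger gene, rose by 1.89 (SE 0.14, adjusted p = 5.76e-05), the growth factor Igf2 by 1.74 (SE 0.15, adjusted p = 0.000115) and the adjacent noncoding RNA gene H19 from a mean of 9.89 to 11.39 (SE 0.17, adjusted p = 0.000384), each in all 4 Gadd45a arrays.

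The neutrophil genes S100a8 and S100a9 had log2 fold changes of -2.03 (adjusted p = 0.087) and -1.95 (adjusted p = 0.078). They did not pass, and Gadd45a 3 stood apart from the other Gadd45a arrays, at 8.59 for S100a8 against 4.18, 6.49 and 5.53, and at 9.29 for S100a9 against 5.58, 7.7 and 5.86. Ngp, a granule gene, had -1.29 (adjusted p = 0.0855), with 7.1 in Gadd45a 3. The values in Gadd45a 3 were close to those in control 3, at 8.61 for S100a8, 9.42 for S100a9 and 7.07 for Ngp. Without Gadd45a 3, S100a8, S100a9 and Ngp passed, at -2.83, -2.68 and -1.85 (adjusted p = 0.00588, 0.00589 and 0.001). The smallest changes were -1.36 for S100a8 and -1.43 for S100a9 without the arrays numbered 1. For Ngp the smallest was -0.96, without those numbered 4. With all arrays, S100a8, S100a9 and Ngp also passed when probe sets below the median brightness were left out (adjusted p = 0.0434, 0.0375 and 0.0425), where fewer probe sets are tested and the log2 fold changes are the same.

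A hypothesis from the first of these patterns was that imprinted genes in general may be higher with Gadd45a plasmid. Of the 3 held-out lists tried in all, the one of 34 other imprinted genes, written before its test, had 23 measured members, of which 5 rose (Plagl1 by 1.00, Cdkn1c by 0.85, Igf2r by 0.71, Rtl1 by 0.41 and Impact by 0.36) and 1 fell (Asb4, -0.47). Of these, Asb4, Impact and Rtl1 lost their calls in 10, 8 and 5 of the 12 fits without an array or a pair. The list missed its threshold (camera p = 0.0503, and p = 0.111 with an estimated correlation; median 0.03). Without control 4 the p was 0.13, the highest, and without control 2 it was 0.0192, the lowest. A second test, of whether a single array or pair decides the result, could not tell, since its threshold was already missed with all arrays. The threshold set beforehand was therefore missed; that the p lies within this range was weighed only after it was seen, and a general rise of imprinted genes was not shown.

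A second hypothesis, from the lower Tgtp1, Gbp7, Gbp2 and Gbp3, was that the interferon-gamma response may be lower. The held-out list left those genes out. Of its 19 genes only 4 were measured, Irgm1 (-0.95, SE 0.18), Ido1 (-0.89, SE 0.12), Gbp5 (-0.88, SE 0.17) and Socs1 (-0.42, SE 0.11, a call lost in 6 of the 12 fits without an array or a pair), and all 4 fell (camera p = 0.00128; 0.000331 to 0.00339 without an array or a pair; p = 0.0964 with an estimated correlation). With only 4 genes measured, and p = 0.0964 in camera with an estimated correlation, the hypothesis stays open. The fixed list of antigen presentation and interferon genes did not pass (camera adjusted p = 0.811).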
